A study of Homo sapiens with 12 samples.

How the data were processed

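Messenger RNA was sequenced from D283 cells, a medulloblastoma line with amplified MYC, in a control group that received a scrambled construct and in a group with genetic inactivation of the kinase genes ABL1 and ABL2. The method of inactivation is not given in the sources used here. Per the labels, total RNA was extracted with the RNeasy Plus Mini Kit, mRNA was enriched, libraries were built with the KAPA mRNA HyperPrep Kit and 50 bp paired-end reads were made on an Illumina NovaSeq instrument. The 12 samples of the series are 6 libraries sequenced on 2 lanes each, 3 libraries per group.

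The authors' processing notes name FastQC 0.11.9, MultiQC 1.11, STAR 2.7.2b, featureCounts 1.6.3 and DESeq2 1.36.0 with the genome build GRCh38.p14. The deposited values are raw counts per gene and lane, whole numbers that were not normalized. The deposited table also gives the summed exon length of each gene in bases, a unit of its own that was used here only to check for a length trend. How strands and reads with several alignments were counted is not given in the sources used here. The table holds 49677 genes, of which 26, among them TTN, PTK2, BIRC6 and NRCAM, have exon strings at the length limit of a spreadsheet cell and no counts; these were left out. Of the remaining 49651 genes, 22423 had no read in any library. A further 5898 entries are alternate copies of genes on alternate loci and took between 0.0366% and 0.0411% of the counts per library. RefSeq annotation of GRCh38.p14 was matched to 43125 genes for biotypes and current symbols.

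The lanes of each library were summed, since lanes of 1 library are not replicates. Libraries held between 33505903 and 49034159 counts, and a gene with no read in a library can hold up to 3 counts at this depth, which is 0.0612 to 0.0895 CPM, counts scaled to the library total. This floor and the counting intervals of ratios cover counting error only. The intervals of log2 fold changes come from the fit and include the spread between libraries. Genes were filtered with filterByExpr by group (minimum count 10, minimum total count 15), scaled by trimmed mean of M values (TMM), and compared with edgeR 4.0.16 by the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are TMM-normalized CPM as mean ± SD of 3 libraries per group, and log2 fold changes (inactivated over control) are given ± SE. In the text, rose, fell and changed are used of genes past this threshold. The fit gave a biological coefficient of variation of 0.0447.

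Before the data were examined, 44 gene lists with 1346 entries, 24 genes of interest, the tests, the other settings to be tried and the rule for the genes to be named were fixed. The named genes are the genes of interest that were tested, with ABL1 and ABL2 first. To these were added the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold, with a mean of at least 5 CPM in the higher group, an official symbol and no overlap between the groups. Each list gave up to 4 members with the lowest p among those past the threshold, or up to 2 by level where none passed. Some genes that this rule gave are not reported here. Genes outside this rule that are named in the closing section were chosen after their values were seen. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 with a preset correlation of 0.01, two-sided, adjusted over the 42 lists tested. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way, without comparing them with other genes.

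Regions along chromosomes were sought after the data were seen. The log2 fold changes of 10085 genes with at least 5 CPM in 1 of the groups, limited to 1.5 in size, were segmented by circular binary segmentation with 500 permutations and at least 15 genes per region. Neighbouring regions whose medians differed by less than 0.2 were joined, and a region with a median of at least 0.2 in size was called shifted. The trend on GC content and gene length was removed by loess with a span of 0.5 for a check, with the GC content of transcripts from GENCODE.

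Tested on simulated data with 200 changed genes, the gene test recovered 83% of genes changed 1.5-fold and 90.0% of genes changed 2-fold. Of its 186 calls 6.99% were genes that had not been changed, somewhat above the nominal 5%. In the real data 59.3% of the tested genes changed, a far larger share that was not simulated. In a simulation with 1 list raised 1.5-fold, camera called that list and no other. Its genes were drawn independently of each other, so it cannot tell whether the preset correlation holds for the real lists. The segmentation found 0 shifted regions when the gene order was shuffled, and both of 2 planted regions with 99.4% of their genes. The planted log2 shift was 0.5 in size, and the recovery of weaker shifts was not tried.

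Beside the main settings 23 others were fixed beforehand and 1 was added after seeing the data. The former covered other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, a robust fit and a stricter threshold. They also covered a test against a fold of 1.5, single lanes, lanes as samples, protein-coding genes only, no mitochondrial genes, other list tests and leaving out each replicate. The added one refitted the data without the genes of the shifted regions. All 10 splits of the 6 libraries into 3 and 3 were fitted. Computations used R 4.3.3, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. Genes on the Y chromosome, XIST and TSIX were tested with the rest and are not reported. No DNA or protein measurement was used here.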

Results

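The series asks about the role of ABL kinases in medulloblastoma, and its labels give 1 comparison, D283 cells with ABL1 and ABL2 inactivated against cells with a scrambled control. RNA sequencing counts were obtained for 3 control libraries with 35893081, 34951232 and 33505903 counts and 3 inactivated libraries with 36140406, 49034159 and 34292341 counts. Counts of the lanes of a library differed by little more than sampling, with a chi-square of 1.13 to 1.21 per degree of freedom. Libraries of the same group gave 3.17 to 13.6, and libraries of different groups 86.7 to 111. The first principal component held 85.5% of the variance and separated the groups. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

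ABL1 and ABL2 mRNA were both lower in all 3 inactivated libraries than in any control library, ABL1 more so than ABL2. ABL1, a tyrosine kinase gene on the forward strand of chromosome 9 at 130713043 to 130887675 (GRCh38.p14), had 157, 148 and 154 CPM in the control libraries and 62.1, 62.3 and 61.1 CPM in the inactivated ones. Its mean fell from 153 ± 4.82 to 61.9 ± 0.625 CPM (mean ± SD, n = 3 per group here and below), which is 59.6% lower. By edgeR's quasi-likelihood test its log2 fold change was -1.31 ± 0.043 (SE), with a 95% interval of -1.40 to -1.22 and an adjusted p of 5.4e-15 after Benjamini-Hochberg correction. ABL2, its close relative on the reverse strand of chromosome 1 at 179099330 to 179229677, had 144, 136 and 134 CPM in the control libraries and 97.6, 112 and 102 CPM in the inactivated ones. Its mean fell from 138 ± 5.58 to 104 ± 7.598 CPM, which is 24.6% lower, with a log2 fold change of -0.41 ± 0.051, a 95% interval of -0.52 to -0.30 and an adjusted p of 1.3e-06 in the same test. ABL2 lies in a part of chromosome 1 whose genes had a median log2 fold change of 0.33, and relative to that median its log2 fold change was -0.74. These values measure mRNA alone.

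**Figure D1:**
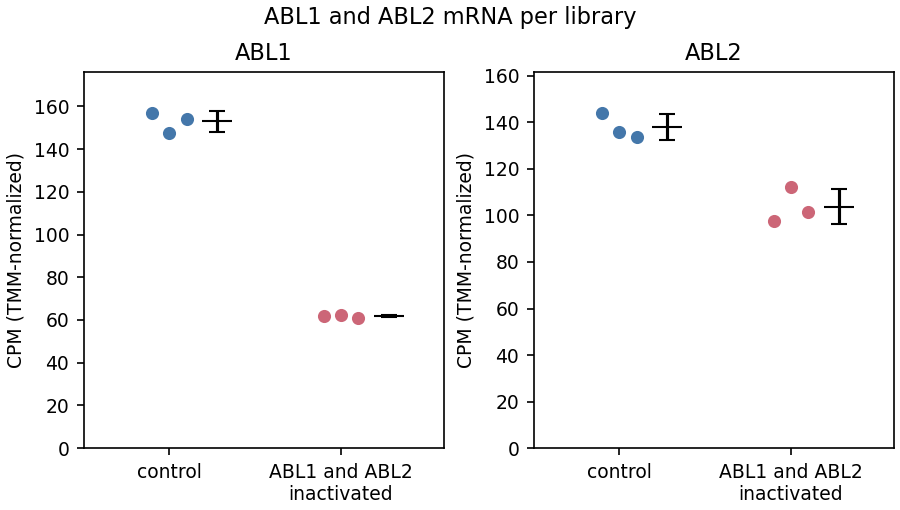
Level of ABL1 and ABL2 mRNA in each library in TMM-normalized CPM, with 1 point per library (blue control, red inactivated) and a bar for the mean ± SD of 3 libraries. ABL1 lies at 148 to 157 CPM in the control libraries and 61.1 to 62.3 CPM in the inactivated ones, and ABL2 at 134 to 144 against 97.6 to 112 CPM.

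Of 14704 genes tested, 8726 (59.3%) changed, 4352 higher and 4374 lower in the inactivated cells. Most changes were small: 5197 of the changed genes differed by less than 1.5-fold, and 1886 differed by at least 2-fold, 932 higher and 954 lower. Among protein-coding genes 7757 of 12291 changed. The levels of the groups did not overlap for 9294 genes (63.2%), where chance gives 10%. Against a fold of 1.5 as the null, the number of changed genes was 2280.

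**Figure D2:**
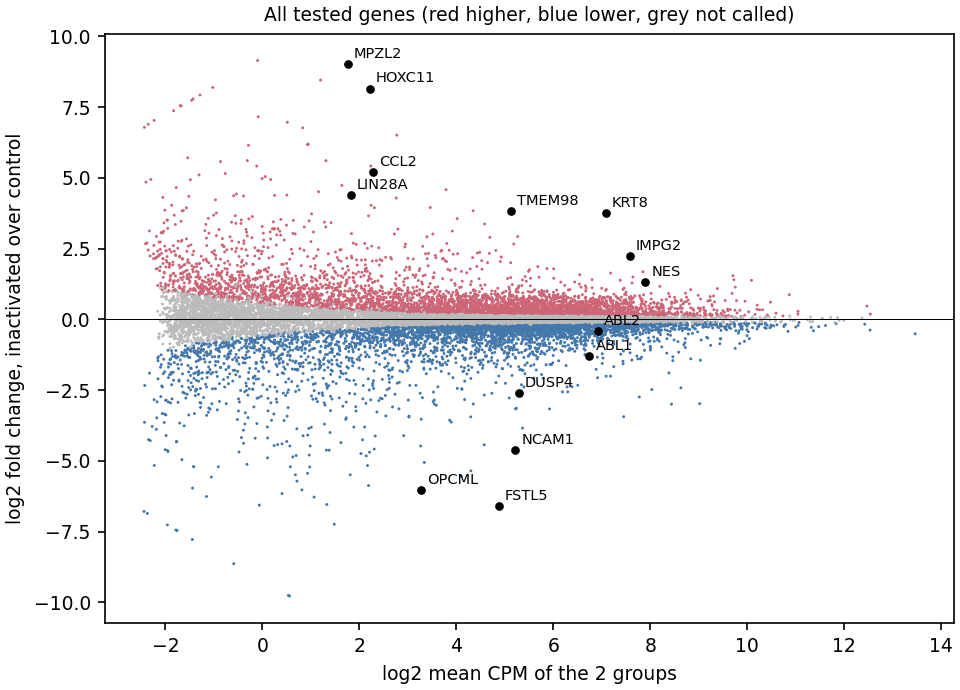
Fitted log2 fold change (inactivated over control) of each tested gene against the log2 of its mean CPM over both groups, red for genes that rose, blue for genes that fell, grey for genes not past the threshold, with named genes in black. ABL1 and ABL2 lie at -1.31 and -0.41, and the positions of MPZL2 and HOXC11, with 1 and 3 control counts, depend on the fit and are no measure of their fold.

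Genes that fell most included neuronal adhesion and synapse genes. FSTL5, a follistatin-like gene used as a marker of Group 4 medulloblastoma, fell from 57.99 ± 3.57 to 0.598 ± 0.208 CPM (log2 fold change -6.59 ± 0.11). OPCML, a neural cell adhesion gene, fell from 18.9 ± 1.09 to 0.307 ± 0.205 CPM, and CNTNAP5, a contactin-associated gene, from 19.7 ± 0.807 to 0.567 ± 0.181 CPM. DCLK1, a microtubule-associated kinase of migrating neurons, fell from 8.55 ± 0.385 to 0.284 ± 0.114 CPM, and SNAP91, which acts in synaptic vesicle recycling, from 7.89 ± 0.184 to 0.293 ± 0.0791 CPM. FGF13, which regulates sodium channels, fell from 8.91 ± 0.393 to 0.3399 ± 0.0171 CPM, and the chloride transporter CLCN4 from 33.7 ± 1.33 to 0.721 ± 0.0496 CPM. DMRTA1, a transcription factor gene, fell from 5.55 ± 0.102 CPM to a mean of 0.0377 CPM, below the counting floor, so the size of its fold is not known. The other genes of the 12 largest decreases were JHY, L3MBTL4, INSYN2A and UGT8, with log2 fold changes of -5.88, -5.50, -5.36 and -5.17.

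Among the largest increases were genes at or near the counting floor in control cells. MPZL2, an epithelial adhesion gene, had 1 count in the control group and 810 in the inactivated group, a ratio of 708 with a 95% counting interval of 127 to 27980. HOXC11, a homeobox gene, had 3 against 1116 counts, a ratio of 325 with an interval of 111 to 1578. KRT8, a keratin of simple epithelia, rose from 18.6 ± 1.21 to 252 ± 20.1 CPM (log2 fold change 3.76 ± 0.064), and the membrane protein gene TMEM98 from 4.56 ± 0.258 to 65.04 ± 3.11 CPM. OTOGL, an otogelin-like gene, rose from 0.147 ± 0.0805 to 13.5 ± 0.876 CPM, and LIN28A, an RNA-binding protein of stem cells that blocks let-7 maturation, from 0.317 ± 0.0671 to 6.75 ± 0.416 CPM. CCL2, a chemokine that attracts monocytes, rose from 0.251 ± 0.0327 to 9.45 ± 1.08 CPM, ITGA5, the fibronectin receptor subunit, from 0.546 ± 0.207 to 8.91 ± 0.177 CPM, and GIP, an incretin hormone gene, from 0.5999 ± 0.0738 to 9.31 ± 0.665 CPM. LINC02463, HTATSF1P2 and GLRA4 had log2 fold changes of 4.58, 4.73 and 4.29. HTATSF1P2 and GLRA4 are annotated as pseudogenes, whose reads can come from related genes.

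Genes in 6 stretches of the genome shifted together, a pattern sought after the data were seen. On chromosome 1 the 263 genes from 169783837 to 248930191 had a median log2 fold change of 0.33. The 459 genes of chromosome 6 from 292487 to 170584637, nearly the whole chromosome, had a median of 0.50, and the 405 genes of chromosome 17 from 30248203 to 82945914 had a median of 0.48. Lower were 71 genes of chromosome 3 from 2098866 to 18445592 with a median of -0.62, and 59 genes of chromosome 7 from 64313961 to 84492725 with a median of -1.12. On chromosome 12, 37 genes from 51186936 to 54419266, which include the HOXC cluster and keratins, had a median of 0.20. These regions held 1875 genes, 12.9% of the tested genes with a position on chromosomes 1 to 22 or X, and 79.8% of the genes inside them changed against 56.7% elsewhere. Of the named genes above, CCL2, GIP and TMEM98 lie in the chromosome 17 region, HTATSF1P2 and SNAP91 in that of chromosome 6, and KRT8, HOXC11 and ITGA5 in that of chromosome 12.

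**Figure D3:**
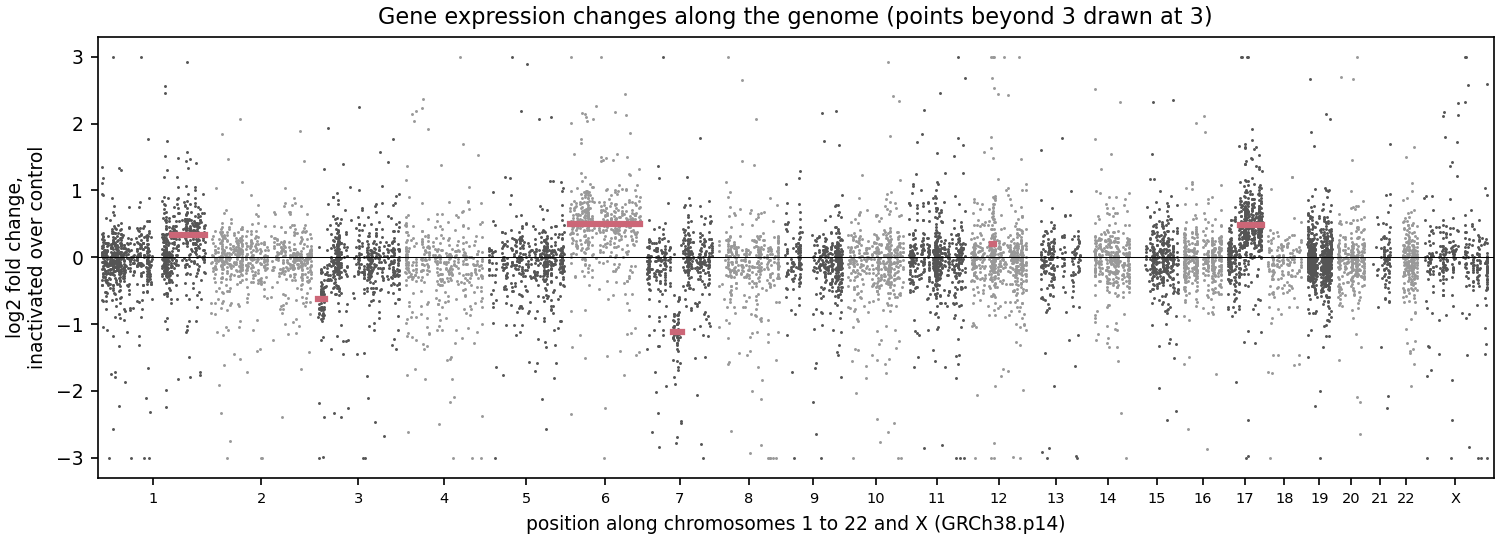
Log2 fold change (inactivated over control) of genes with at least 5 CPM in 1 of the groups, by position along chromosomes 1 to 22 and X, with grey shades alternating between chromosomes and values beyond 3 drawn at 3. Red bars mark the 6 shifted regions at their median, from -1.12 on chromosome 7 to 0.50 on chromosome 6.

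Genes of interest in medulloblastoma moved in both directions. OTX2, a homeobox oncogene of Group 3 tumours, fell from 829.8 ± 16.1 to 666 ± 11.4 CPM, the cyclin gene CCND2 from 865 ± 17.7 to 539 ± 19.4 CPM, and NEUROD1, a neurogenic transcription factor, from 28.5 ± 1.51 to 17.8 ± 1.06 CPM. CDKN1A, which encodes the cell cycle inhibitor p21, fell from 17.2 ± 0.479 to 10.03 ± 1.07 CPM, although it lies in the region of chromosome 6 with higher medians. E2F1 fell from 58.1 ± 0.382 to 46.9 ± 1.13 CPM, the intermediate filament gene VIM from 872 ± 15.2 to 714 ± 33.5 CPM, and PROM1, a surface marker of progenitor cells, from 251 ± 9.14 to 204 ± 3.96 CPM. NES, the intermediate filament of neural progenitors, rose from 138 ± 4.69 to 339 ± 0.159 CPM, and FN1, which encodes fibronectin, from 4.52 ± 0.431 to 16.9 ± 1.358 CPM. The proliferation marker MKI67 rose from 337 ± 26.7 to 522 ± 7.403 CPM and the mitotic kinase AURKA from 82.97 ± 1.91 to 107 ± 4.12 CPM. BIRC5, a survivin gene in the chromosome 17 region, rose from 159 ± 0.931 to 221 ± 13.3 CPM. MYC rose from 482 ± 19.2 to 526 ± 29.1 CPM with an adjusted p of 0.0289 in edgeR's test, a 1.09-fold change with overlapping groups.

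Some calls were lost when 1 library was left out, with fold changes of the same sign. The MYC call was lost without control replicate 1, control replicate 2, inactivated replicate 1 or inactivated replicate 3 (edgeR adjusted p of 0.0905, 0.102, 0.0831 and 0.136). CD44, a hyaluronan receptor, rose from 142 ± 0.479 to 154 ± 5.099 CPM with an adjusted p of 0.022, which became 0.0752 without control replicate 2, 0.0555 without control replicate 3 and 0.114 without inactivated replicate 3. TUBB3, a neuronal tubulin, rose from 4.78 ± 0.4600 to 5.91 ± 0.255 CPM with an adjusted p of 0.0172, and of 0.0807, 0.0553 and 0.0563 without control replicate 1, control replicate 3 and inactivated replicate 1. Not past the threshold were the mitotic kinase gene PLK1 (log2 fold change 0.10 ± 0.044), CDK6 (0.11 ± 0.055), MYCN (-0.49 ± 0.29), BCL2L11 (0.11 ± 0.069) and HSF1 (0.18 ± 0.22). PLK1 passed without inactivated replicate 2 (adjusted p 0.00561), CDK6 without control replicate 1 (0.0337) or inactivated replicate 1 (0.0102), and MYCN without control replicate 1 (0.0471). CCND1 had too few counts to be tested.

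Of the 44 lists 42 had enough expressed genes for a test, and 19 of these were called with camera's preset correlation, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05. Fry called 30. For each called list, the median, the mean and the test had the same sign. In the paragraphs that follow, members are counted by edgeR's test adjusted over all genes, and the count adjusted over the list alone is given for each list for which it differs; for the others, the counts adjusted over the list alone were equal.

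**Figure D4:**
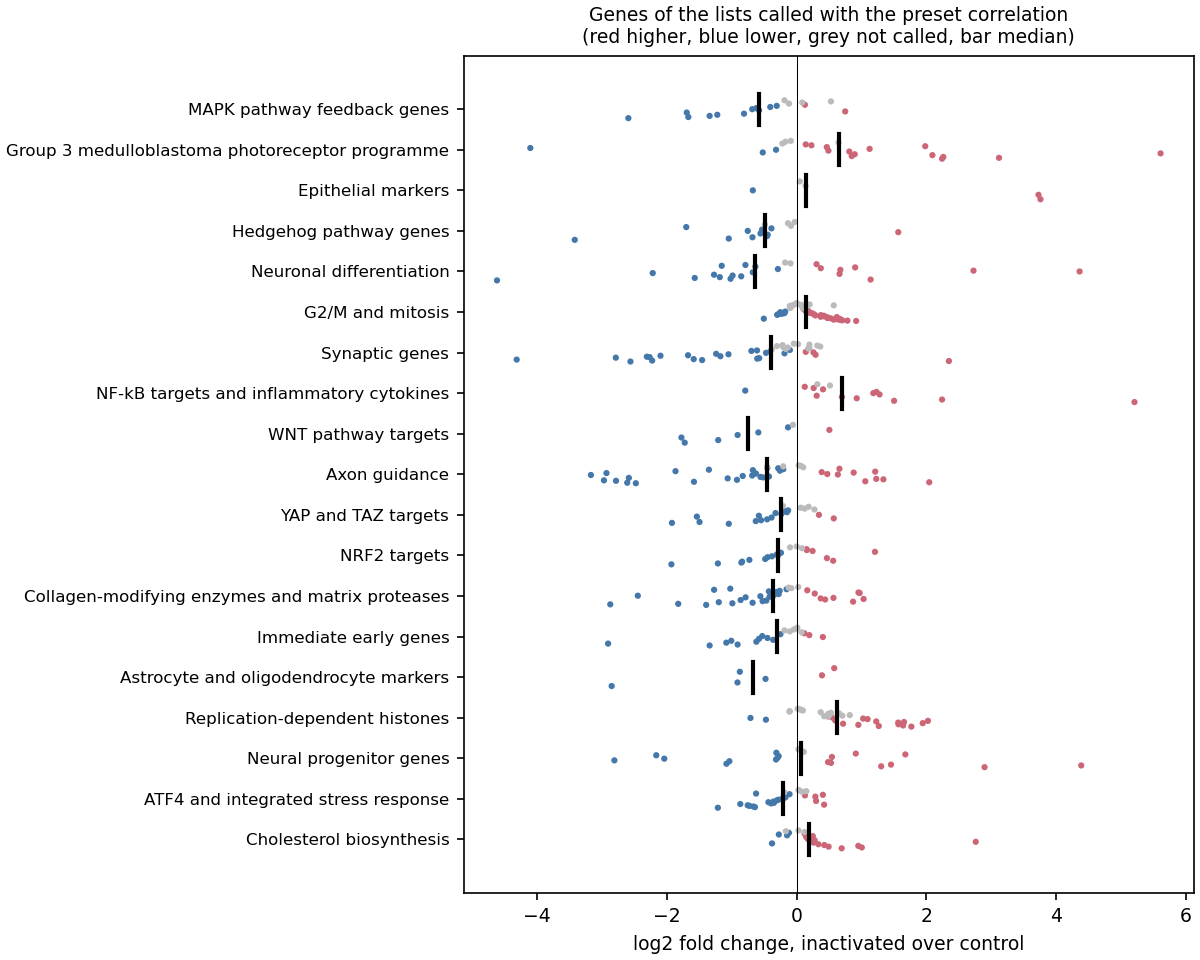
Log2 fold change (inactivated over control) of the tested members of each of the 19 lists called by camera with the preset correlation, 1 point per gene, red for genes that rose, blue for genes that fell and grey for genes not past the threshold, with a black bar at the list's median. Medians run from -0.75 for the WNT pathway targets to 0.70 for the NF-kB targets.

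Genes that ERK signalling induces as its own feedback fell as a group. Of 17 MAPK pathway feedback genes, 11 fell, 2 rose and 4 did not pass, with a median log2 fold change of -0.58 (camera adjusted p 2.5e-06, and adjusted p = 0.194 with an estimated correlation). DUSP4, a phosphatase that inactivates ERK, fell from 66.9 ± 0.713 to 11.1 ± 0.562 CPM, PHLDA1 from 231 ± 3.07 to 72.6 ± 4.29 CPM, and ETV5, a transcription factor downstream of ERK, from 67.2 ± 1.902 to 28.8 ± 1.364 CPM. Among 20 immediate early genes, 11 fell, 3 rose and 6 did not pass (median -0.31, adjusted p 0.0262, and adjusted p = 0.37 with an estimated correlation). EGR1 fell from 53.3 ± 1.94 to 21.01 ± 0.732 CPM, FOS from 11.9 ± 0.416 to 5.57 ± 0.968 CPM, FOSB from 3.88 ± 0.6304 to 0.509 ± 0.0879 CPM and KLF10 from 104 ± 1.02 to 55.1 ± 0.701 CPM; the call was lost in lane 2 alone (adjusted p 0.0628). Of the 21 YAP and TAZ targets 14 fell and 2 rose, and 5 did not pass (median -0.24, adjusted p 0.00875, and adjusted p = 0.251 with an estimated correlation). They included CRIM1, which fell from 89.5 ± 0.833 to 43.4 ± 0.921 CPM, and IGFBP3, an IGF-binding protein, which fell from 16.5 ± 0.6003 to 4.35 ± 0.431 CPM. GADD45B fell from 17.9 ± 1.31 to 6.38 ± 0.667 CPM and WWC1, an activator of the Hippo pathway, from 83.2 ± 0.673 to 53.8 ± 1.25 CPM.

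The ABL signalling partners, adaptors and substrates of the kinases, did not move one way. 8 of 20 rose, 7 fell and 5 did not pass (adjusted p 0.406), with a median of -0.036 while the mean of 0.082 and the test pointed up. GRB2, an adaptor of receptor signalling, rose from 111 ± 1.66 to 178 ± 5.05 CPM, and STAT5B, a transcription factor phosphorylated by ABL fusion kinases, from 24.7 ± 0.527 to 43.7 ± 0.199 CPM, both in the chromosome 17 region. ABI1, an ABL interactor, rose from 53.6 ± 1.101 to 83.4 ± 0.546 CPM and EVL, an actin regulator, from 37.6 ± 1.29 to 60.8 ± 1.98 CPM.

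Of developmental pathways with known roles in medulloblastoma, Hedgehog genes and WNT targets were mostly lower, and NOTCH and TGF-beta targets went both ways. Of 15 Hedgehog pathway genes 10 fell, 1 rose and 4 did not pass (median -0.49, adjusted p 0.00311, and adjusted p = 0.37 with an estimated correlation). The co-receptor genes GAS1 and CDON fell from 14.9 ± 0.667 to 1.38 ± 0.0462 CPM and from 114 ± 2.83 to 54.97 ± 2.83 CPM, and PTCH1, the Hedgehog receptor and target, from 50.6 ± 2.07 to 36.9 ± 1.88 CPM. 6 of 8 WNT pathway targets fell, 1 rose and 1 did not pass (median -0.75, adjusted p 0.00781, and adjusted p = 0.271 with an estimated correlation). APCDD1, a WNT antagonist, fell from 18.3 ± 0.955 to 5.54 ± 0.5502 CPM, LGR5, an R-spondin receptor, from 9.87 ± 0.497 to 2.88 ± 0.328 CPM, BMP4 from 29.4 ± 0.659 to 12.7 ± 0.684 CPM and TCF7 from 12.2 ± 0.228 to 6.51 ± 0.918 CPM. The NOTCH targets were not called (5 rose, 4 fell and 4 of 13 did not pass, median 0.27, adjusted p 0.608): JAG2, a NOTCH ligand, rose from 26.3 ± 1.31 to 51.2 ± 0.428 CPM and the feedback regulator NRARP from 9.85 ± 1.13 to 18.8 ± 0.983 CPM, while HES1, a repressor induced by NOTCH, fell from 15.98 ± 1.605 to 7.58 ± 0.627 CPM and the ligand gene JAG1 from 24.7 ± 1.27 to 17.1 ± 1.05 CPM. Nor were the TGF-beta and BMP targets called (6 rose, 5 fell and 2 of 13 did not pass, median 0.075, adjusted p 0.582). LTBP2, a TGF-beta binding protein, fell from 38.1 ± 1.68 to 14.96 ± 0.565 CPM, while SKIL rose from 125 ± 2.87 to 191 ± 13.8 CPM and BAMBI from 26.4 ± 1.07 to 42.3 ± 2.69 CPM.

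Photoreceptor genes, a programme known from Group 3 medulloblastoma, rose as a group. Of 21 tested, 14 rose, 3 fell and 4 did not pass, against 15 and 4 adjusted over the list alone (median 0.65, adjusted p 9.0e-06, and adjusted p = 0.194 with an estimated correlation). IMPG2, a proteoglycan of the photoreceptor matrix, rose from 66.7 ± 3.63 to 316 ± 18.4 CPM, and ABCA4, a retinal transporter, from 3.12 ± 0.283 to 27.1 ± 1.55 CPM. EYS rose from 4.09 ± 0.264 to 19.6 ± 1.19 CPM, in the chromosome 6 region, which with the other regions held 4 members of the list. MAB21L2, an eye development gene, rose from 363 ± 5.57 to 654 ± 28.3 CPM. Among 11 Group 4 markers 4 rose, 4 fell and 3 did not pass (adjusted p 0.942); their median was -0.0042 and their mean -0.44, while the test pointed up. SNCAIP, which encodes a synuclein-binding protein, rose from 8.82 ± 0.745 to 37.2 ± 0.847 CPM, while FSTL5 and GRM8 fell, GRM8 from 7.99 ± 0.191 to 5.05 ± 0.746 CPM.

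Neuronal genes were lower in 3 lists. Of 23 neuronal differentiation genes 13 fell, 8 rose and 2 did not pass (median -0.64, adjusted p 0.00444, and adjusted p = 0.271 with an estimated correlation). NCAM1, the neural cell adhesion molecule, fell from 71.1 ± 1.16 to 2.86 ± 0.252 CPM, the neurofilament gene NEFM from 259.9 ± 30.6 to 87.5 ± 2.91 CPM and the neuronal enolase ENO2 from 120.2 ± 0.9204 to 59.3 ± 0.556 CPM, while DPYSL3, a growth cone protein, rose from 539 ± 12.3 to 1189 ± 17.8 CPM. 21 of 38 synaptic genes fell, 4 rose and 13 did not pass, against 23 and 4 adjusted over the list alone (median -0.40, adjusted p 0.00758, and adjusted p = 0.251 with an estimated correlation). GRIN2A, an NMDA receptor subunit, fell from 125 ± 6.41 to 21.1 ± 1.32 CPM and UNC13A, a vesicle priming factor, from 11.7 ± 0.781 to 2.49 ± 0.144 CPM, whereas the vesicle protein SV2B rose from 7.104 ± 0.416 to 36.2 ± 1.93 CPM. Among 38 axon guidance genes 23 fell, 10 rose and 5 did not pass (median -0.45, adjusted p 0.00781, and adjusted p = 0.37 with an estimated correlation). SEMA3A and SEMA3C, repulsive or attractive guidance cues in the chromosome 7 region, fell from 444 ± 13.8 to 79.6 ± 3.81 CPM and from 50.2 ± 2.23 to 16.8 ± 0.599 CPM, and SLIT1 fell from 45.7 ± 2.52 to 7.47 ± 0.185 CPM, while SLIT2 rose from 11.7 ± 0.542 to 48.3 ± 2.38 CPM. Without the genes of the shifted regions the axon guidance call was lost (median -0.41, adjusted p 0.134), and with limma-voom the neuronal differentiation call (adjusted p 0.0836).

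Neural progenitor genes split evenly. 9 of 22 rose, 9 fell and 4 did not pass, against 10 and 9 adjusted over the list alone (median 0.064, adjusted p 0.028 upward, and adjusted p = 0.404 with an estimated correlation). NR2F1, a nuclear receptor of cortical patterning, rose from 6.13 ± 0.882 to 45.6 ± 1.63 CPM and LIN28B from 24.7 ± 1.44 to 67.8 ± 4.51 CPM. The regions held 6 members, and without region genes the call was lost with a median of -0.11 (adjusted p 0.149), as it was with limma-voom (0.503). All 6 tested astrocyte and oligodendrocyte markers changed, 4 lower and 2 higher (median -0.68, adjusted p 0.0262, and adjusted p = 0.414 with an estimated correlation); the call was lost with limma-voom (0.169). SLC1A2, a glutamate transporter, fell from 14.2 ± 0.162 to 1.95 ± 0.123 CPM, and SLC1A3, another of this family, from 75.9 ± 1.32 to 54.4 ± 0.841 CPM. CNP, in the chromosome 17 region, rose from 95.2 ± 1.28 to 125 ± 2.64 CPM.

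Mitotic genes rose by small amounts. Of 56 G2/M and mitosis genes 32 rose, 7 fell and 17 did not pass, against 37 and 8 adjusted over the list alone (median 0.15, adjusted p 0.00629, and adjusted p = 0.37 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, rose from 571 ± 21.9 to 1079 ± 49.1 CPM, the kinesin KIF14 from 91.4 ± 2.88 to 157 ± 8.04 CPM, the checkpoint kinase TTK from 88.8 ± 4.63 to 145 ± 2.81 CPM and the kinetochore protein CENPF from 466 ± 3.59 to 743 ± 48.7 CPM. These 4 lie in regions with higher medians, which held 10 of the 56 genes, and without region genes the list was still called (median 0.14, adjusted p 0.0303). DNA replication and G1/S genes went both ways, with 14 of 46 higher, 17 lower and 15 not past the threshold (median -0.017, adjusted p 0.942). E2F8 rose from 6.78 ± 0.581 to 22.5 ± 0.283 CPM and the primase subunit PRIM1 from 39.6 ± 1.73 to 57.2 ± 1.07 CPM, while the phosphatase gene CDC25A fell from 156 ± 2.91 to 114 ± 3.59 CPM and RFC2, a clamp loader in the chromosome 7 region, from 97.6 ± 3.09 to 45.6 ± 2.33 CPM. Replication-dependent histones, whose mRNAs mostly lack poly(A) tails, had 15 of 32 members higher, 2 lower and 15 not past the threshold, against 14 and 2 adjusted over the list alone. Their median was 0.62 (adjusted p 0.0272, and adjusted p = 0.764 with an estimated correlation), and H2BC12 rose from 6.43 ± 0.631 to 21.96 ± 1.25 CPM and H2BC5 from 3.903 ± 0.474 to 9.41 ± 0.521 CPM. Of these histone genes 27 lie in shifted regions, the 5 others had a median of 0.042 (adjusted p 0.799), and without inactivated replicate 1 the call was lost with a median of 0.36 (adjusted p 0.0669). It was also lost in lane 1 alone (0.0551), in lane 2 alone (0.0511) and with lanes as samples (0.0724).

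Growth-related lists were not called. Of 53 MYC targets and ribosome biogenesis genes 21 fell, 11 rose and 21 did not pass (median -0.081, adjusted p 0.942). PHB1 and NME1 rose from 231 ± 5.34 to 372 ± 19.5 CPM and from 124 ± 1.74 to 178 ± 14.4 CPM, both in the chromosome 17 region. Among 76 cytosolic ribosomal protein genes 45 fell, 8 rose and 23 did not pass, none by 2-fold (median -0.17, adjusted p 0.0769). RPL32 fell from 1243 ± 54.6 to 725 ± 63.4 CPM in the chromosome 3 region, RPL39 fell from 137 ± 1.45 to 102 ± 4.73 CPM, and RPL23 rose from 978 ± 33.2 to 1386 ± 84.7 CPM in the chromosome 17 region. The ribosomal list passed without control replicate 1 (adjusted p 0.0448) or inactivated replicate 1 (0.00674), and reads of its genes are hard to tell from those of their many pseudogenes. Nuclear-encoded oxidative phosphorylation genes had 15 of 64 members higher, 10 lower and 39 not past the threshold, against 12 and 7 adjusted over the list alone (median 0.026, adjusted p 0.574). ATP5MC1, a subunit of ATP synthase in the chromosome 17 region, rose from 90.5 ± 6.25 to 159 ± 15.2 CPM and NDUFC2, of complex I, from 39.8 ± 1.55 to 57.1 ± 2.76 CPM. Of 13 mitochondrially encoded mRNAs 1 rose, 2 fell and 10 did not pass (median -0.014, adjusted p 0.942): MT-CO1 fell from 6710.4 ± 859.8 to 5159 ± 581 CPM and MT-ND5 from 3011 ± 337 to 2272 ± 349 CPM, and MT-ND6 rose from 257 ± 35.05 to 328 ± 92.4 CPM. The MT-ND6 call was lost without control replicate 2 (adjusted p 0.147), control replicate 3 (0.0947) or inactivated replicate 2 (0.123, with a log2 fold change of 0.11). The MT-ND6 call was also lost with DESeq2 (MT-ND6 log2 fold change with an adjusted p of 0.292) and with the robust fit (0.291), as was that of MT-ND5 with the robust fit (MT-ND5 log2 fold change with an adjusted p of 0.0588).

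Stress and metabolic programmes differed in direction. Of 21 NRF2 targets 12 fell, 6 rose and 3 did not pass (median -0.28, adjusted p 0.0113, and adjusted p = 0.414 with an estimated correlation). HMOX1, which breaks down haem, fell from 29.5 ± 1.67 to 7.74 ± 0.543 CPM, the ferritin heavy chain FTH1 from 1184 ± 18.6 to 656 ± 29.3 CPM and the quinone reductase NQO1 from 90.8 ± 1.05 to 50.8 ± 3.196 CPM. 19 of 30 ATF4 and integrated stress response genes fell, 6 rose and 5 did not pass (median -0.20, adjusted p 0.0353, and adjusted p = 0.696 with an estimated correlation). SLC7A11, the cystine transporter shared with the NRF2 list, fell from 64.3 ± 3.41 to 27.6 ± 1.78 CPM, and PPP1R15A, a phosphatase subunit that ends the stress response, from 62.6 ± 3.55 to 39.4 ± 1.86 CPM. The ATF4 call was lost with a filter of at least 1 CPM in 3 libraries (adjusted p 0.0671) and with protein-coding genes only (0.0739). Cholesterol biosynthesis genes were higher, with 16 of 23 up, 4 down and 3 not past the threshold, against 17 and 5 adjusted over the list alone. Their median was 0.18 (adjusted p 0.0353, and adjusted p = 0.513 with an estimated correlation), and the call was lost with the 1 CPM filter (0.0606) and in lane 2 alone (0.0542). The sterol synthesis enzymes LSS and TM7SF2 rose from 5.66 ± 0.868 to 10.98 ± 0.847 CPM and from 5.84 ± 0.377 to 11.7 ± 0.822 CPM.

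Other stress lists were not called. Endoplasmic reticulum chaperones had 14 of 23 members lower, 3 higher and 6 not past the threshold (median -0.17, adjusted p 0.107), among them PDIA4, which fell from 266 ± 4.42 to 118 ± 1.400 CPM. Hypoxia and glycolysis genes had 15 of 36 lower, 11 higher and 10 not past the threshold (median -0.079, adjusted p 0.195). The hexokinase gene HK1 fell from 94.5 ± 5.49 to 32.6 ± 1.32 CPM, PDK1 from 34.7 ± 1.07 to 19.4 ± 1.06 CPM and the phosphofructokinase gene PFKM from 91.6 ± 1.89 to 61.4 ± 1.52 CPM. For the heat shock response 7 of 20 genes rose, 4 fell and 9 did not pass (adjusted p 0.942), and the mean of -0.018 had the other sign than the median of 0.073 and the test. The small heat shock protein CRYAB fell from 255 ± 12.5 to 91.5 ± 8.22 CPM and HSP90AB1 rose from 4755 ± 81.9 to 6581 ± 149 CPM, the latter in the chromosome 6 region. Lysosome and autophagy genes had 16 of 31 lower, 8 higher and 7 not past the threshold (median -0.14, adjusted p 0.523), with LAMP2, a lysosomal membrane protein gene, falling from 199 ± 3.11 to 142 ± 2.55 CPM.

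Inflammatory genes rose as a group, and the list of interferon-stimulated genes, more of which fell than rose, was not called. Of 15 NF-kB targets and inflammatory cytokines 12 rose, 1 fell and 2 did not pass (median 0.70, adjusted p 0.00761, and adjusted p = 0.251 with an estimated correlation). Beside CCL2, TNFAIP3, an inhibitor of NF-kB signalling, rose from 2.14 ± 0.325 to 6.05 ± 0.564 CPM and TNFAIP2 from 0.308 ± 0.0506 to 1.49 ± 0.388 CPM. Regions with higher medians held 6 of the 15 genes, and without region genes the call was lost (median 0.54, adjusted p 0.134). 14 of 26 interferon-stimulated genes fell, 7 rose and 5 did not pass (median -0.35, adjusted p 0.0726, and 0.0417 without inactivated replicate 3). IFIT5, an interferon-induced RNA-binding protein, fell from 20.97 ± 0.209 to 6.93 ± 0.334 CPM, GBP1, a guanylate-binding protein, from 35.1 ± 1.505 to 14.2 ± 0.505 CPM and DTX3L from 7.37 ± 0.247 to 1.71 ± 0.0853 CPM. MHC class I genes had 3 of 5 lower, 0 higher and 2 not past the threshold (median -0.60, adjusted p 0.0536). B2M, the invariant chain of MHC class I, fell from 19.2 ± 1.27 to 12.7 ± 0.4204 CPM and the peptide-trimming enzyme ERAP2 from 16.98 ± 0.243 to 5.71 ± 0.681 CPM. This list passed without control replicate 2 (adjusted p 0.0483), inactivated replicate 1 (0.0473) or inactivated replicate 3 (0.0442).

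Apoptosis genes and p53 targets were not called as lists. Of 21 pro-apoptotic genes 7 fell, 4 rose and 10 did not pass (median -0.0025, adjusted p 0.942), and the median had the other sign than the mean of 0.42 and the test. With TNFRSF10A at the counting floor the median was the same. CASP8, the initiator caspase of death receptors, rose from 0.0971 ± 0.0202 to 4.86 ± 0.4004 CPM. TNFRSF10A, a TRAIL receptor gene, had 1 control count against 82, a ratio of 71.6 with a 95% counting interval of 12.5 to 2863. BAK1, an effector of mitochondrial apoptosis, fell from 86.1 ± 2.28 to 70.6 ± 4.38 CPM. Among 8 anti-apoptotic genes 2 fell, 1 rose and 5 did not pass (median 0.0060, adjusted p 0.574), with a mean of -0.15 and a test that pointed down. BCL2 fell from 19.2 ± 0.473 to 6.28 ± 1.04 CPM and BCL2L1 from 177 ± 2.85 to 132 ± 4.44 CPM. Of 26 p53 targets 14 fell, 8 rose and 4 did not pass (median -0.14, adjusted p 0.953), with 8 in shifted regions. PPM1D and POLH rose from 50.02 ± 1.47 to 83.1 ± 0.0617 CPM and from 38.6 ± 1.31 to 71.1 ± 4.55 CPM in regions with higher medians, and TP53INP1 rose from 24.5 ± 0.362 to 38.5 ± 2.05 CPM.

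Enzymes that modify or cleave the matrix were mostly lower. Of 34 collagen-modifying enzymes and matrix proteases 22 fell, 9 rose and 3 did not pass (median -0.36, adjusted p 0.0152, and adjusted p = 0.49 with an estimated correlation). TIMP3, a metalloproteinase inhibitor, fell from 662 ± 21.8 to 252 ± 8.75 CPM, the gelatinase gene MMP2 from 9.296 ± 0.0483 to 1.27 ± 0.0719 CPM and LOXL1, which crosslinks elastin, from 23.5 ± 1.13 to 11.9 ± 1.09 CPM. Collagens and extracellular matrix genes had 17 of 35 higher, 12 lower and 6 not past the threshold (adjusted p 0.574), with a median of 0.17 but a mean of -0.13 and a test that pointed down. MGP, an inhibitor of calcification, fell from 195 ± 2.41 to 46.6 ± 2.09 CPM and the basement membrane proteoglycan HSPG2 from 47.8 ± 2.29 to 14.2 ± 0.465 CPM, while COL4A5, a basement membrane collagen, rose from 2.83 ± 0.317 to 16.98 ± 1.39 CPM. Integrin and focal adhesion genes had 14 of 29 lower, 8 higher and 7 not past the threshold (median -0.18, adjusted p 0.0769, and 0.0492 without control replicate 3). PARVA, a parvin that links integrins to actin, fell from 116 ± 3.99 to 37.5 ± 0.922 CPM, vinculin (VCL) from 300.5 ± 13.6 to 122 ± 4.21 CPM and ITGA7 from 6.82 ± 0.125 to 0.776 ± 0.219 CPM. Of 13 epithelial to mesenchymal transition markers 6 fell, 5 rose and 2 did not pass (adjusted p 0.942), with a median of 0.0064 but a mean of -0.045 and a test that pointed down. SNAI2, a repressor of epithelial genes, fell from 26.4 ± 0.663 to 9.79 ± 0.383 CPM and the actin-binding gene TAGLN rose from 8.78 ± 0.517 to 30.2 ± 2.22 CPM.

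Markers of other cell types did not move as one. Of 5 tested epithelial markers 2 rose, 1 fell and 2 did not pass (median 0.14, adjusted p 3.5e-04, and adjusted p = 0.251 with an estimated correlation). Beside KRT8, KRT18 rose from 0.2799 ± 0.0263 to 3.76 ± 0.0614 CPM, and the keratin gene KRT7 fell from 1.28 ± 0.156 to 0.812 ± 0.1996 CPM, a call lost without control replicate 1 (adjusted p 0.0872), inactivated replicate 2 (0.0669) or inactivated replicate 3 (0.0529). KRT18 overlaps KRT8 on the other strand and the strand setting is not known, so their rises may not be separate. The chromosome 12 and other regions held 4 of the 5 epithelial markers, and the call of this list was lost with limma-voom (0.169). Fibroblast markers had 2 of 6 higher, 3 lower and 1 not past the threshold (median -0.15, adjusted p 0.732). PDGFRB, a growth factor receptor, fell from 32.8 ± 1.47 to 18.9 ± 0.739 CPM, and COL1A1, in the chromosome 17 region, rose from 8.11 ± 0.583 to 15.1 ± 1.04 CPM. Too few endothelial (4) and macrophage (1) markers were expressed for a list test. KDR, a VEGF receptor, rose from 2.22 ± 0.342 to 8.41 ± 0.6896 CPM and ESAM from 2.61 ± 0.1900 to 4.13 ± 0.248 CPM, while FLT1 fell from 55.4 ± 0.816 to 51.1 ± 1.17 CPM, a call lost without control replicate 1 (adjusted p 0.127), control replicate 2 (0.0563), inactivated replicate 1 (0.0941) or inactivated replicate 2 (0.0610). The macrophage marker CD68 had 0.614 ± 0.233 CPM in control and 0.757 ± 0.277 CPM in inactivated cells and did not pass. Of 9 nuclear-retained RNAs, which track RNA quality, 0 rose, 1 fell and 8 did not pass (adjusted p 0.942). Their median of 0.030 and mean were above 0 while the test pointed down, and NEAT1 fell from 27.9 ± 3.22 to 21.8 ± 2.96 CPM. Mitochondrial ribosomal RNA took 1.45 ± 0.145% of counts in control and 1.02 ± 0.0944% in inactivated libraries.

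Reads of genes that overlap others could not be told apart where the strand setting matters: of 200 named genes 40 overlap a gene on the same strand and 99 a gene on the other strand. Reads shared between related genes such as histones, tubulins and keratins were not resolved.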

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

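The refit without the genes of the shifted regions was chosen after the data were seen; the other 23 alternatives were planned. No paired analysis was possible because nothing in the labels ties a control library to an inactivated one; the replicate numbers only count the libraries within a group. The number of changed genes was 7136 to 9328 under the alternatives within 1.5 times of 8726, and 7923 to 8725 with 1 replicate left out. Tested against a fold of 1.5 it was 2280, with 1128 higher and 1152 lower, a stricter null by construction. The number changed at least 2-fold was 1259 to 2581, and 1949 to 2028 with 1 replicate left out. Between 48.8% and 53.2% of the changed genes were higher, and 0 genes called in both an alternative and the main test had opposite signs. Among the scalings the largest shift of the median of all genes was 0.023, with library size alone. Without the genes of the shifted regions the shift was 0.027. ABL1 kept its call with log2 fold changes of -1.34 to -1.28 (highest adjusted p 4.0e-11), also its range with 1 replicate left out, and ABL2 with -0.47 to -0.36 (7.2e-05), likewise. Without the genes of the shifted regions, ABL2 among them, 7142 genes changed, 6839 of them called in the main test too, 1509 at least 2-fold, and 14 lists were called. The number of lists called was 0 with an estimated correlation and 30 with fry, which included all 19, against 14 to 25 in the other alternatives and 19 to 21 with 1 replicate left out; for fry and the estimated correlation the cause was not tested. Of 193 named genes with a call, 7 lost it in at least 1 alternative, in 35 of 3789 results, and 14 results without a call gained one.

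The list test changed direction in 37 results of 10 lists, and 1 gene changed sign. All had adjusted p of at least 0.274 in the alternative and at least 0.499 in the main test, 0 of the 38 were past the threshold in either, and the cause was not tested. The values are list medians, whose sign need not follow the test. Pro-apoptotic genes had -0.0025 with fry, -0.019 without a filter, 0.00054 with the 1 CPM filter, -0.010 with DESeq2, -0.0041 with limma-voom, 0.0067 in lane 2, 0.0054 with lanes as samples and -0.049 without inactivated replicate 1 (up to 0.015 without control replicate 3). The p53 targets had -0.13 with the 1 CPM filter, -0.12 in lane 1, -0.13 in lane 2, -0.13 with lanes as samples, -0.12 with protein-coding genes only, -0.14 without inactivated replicate 2 and -0.11 without region genes. Heat shock genes had 0.064 without a filter, 0.080 without control replicate 1 and 0.068 without inactivated replicate 1 (0.061 to 0.091 with any 1 replicate left out). Collagens had 0.17 with limma-voom and 0.27 without region genes. DNA replication genes had 0.00033 with protein-coding genes only, 0.011 without inactivated replicate 2 and 0.0058 without region genes (down to -0.036 without inactivated replicate 1). MYC targets had -0.064 with protein-coding genes only and -0.037 without inactivated replicate 2 (-0.10 to -0.031 with any 1 replicate left out). Mitochondrially encoded mRNAs had 0.067 without control replicate 1, 0.067 without inactivated replicate 1, -0.0085 without inactivated replicate 3 and 0.014 without region genes (down to -0.081 without inactivated replicate 2). Nuclear-retained RNAs had 0.16 without control replicate 1, 0.12 without inactivated replicate 3 and 0.11 without region genes (down to -0.11 without inactivated replicate 1). Group 4 markers had -0.035 without control replicate 2, 0.024 without control replicate 3 and -0.13 without region genes. Epithelial to mesenchymal transition markers had -0.11 without inactivated replicate 2 and 0.034 without region genes (-0.22 to 0.0043 with any 1 replicate left out). The log2 fold change of HSF1 was -0.0044 without control replicate 2 and up to 0.41 without another replicate.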

Other observations

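The gene families below and the tests of the breadth of the changes and of the genes that differ at least 16-fold were chosen after the values were seen, and the regions were sought after the data were seen. In all 26 families were looked at, of which 23 had a tested gene. Among 6 LIN28, HMGA2 and IGF2BP genes, which act in or around the let-7 pathway of fetal growth, 5 rose and 0 fell; LIN28B and IGF2BP1 lie in the shifted regions of chromosomes 6 and 17. HMGA2, a chromatin protein of fetal cells, rose from 181 ± 3.29 to 407 ± 4.96 CPM, and IGF2BP1, an mRNA-binding protein, from 428 ± 16.7 to 909.5 ± 43.8 CPM. IGF2BP2 rose from 79.4 ± 2.83 to 97.3 ± 2.06 CPM, and IGF2BP3 had 60.2 ± 0.987 CPM in control and 64.7 ± 1.82 CPM in inactivated cells and did not pass. Of 9 HOXC genes 8 rose, all 9 in the chromosome 12 region. HOXC4 went from 4.67 ± 0.604 to 13.1 ± 0.516 CPM and HOXC10 from 0.262 ± 0.0567 to 2.31 ± 0.293 CPM. HOXC8 had 28.5 ± 2.02 CPM in control and 26.5 ± 0.429 CPM in inactivated cells and did not pass. HOXC4, HOXC5 and HOXC6 overlap from a shared start at 54016888, so their rises may not be separate. HOXC12 and HOXC13 had control means of 0 and 0.0783 CPM, at the counting floor. Of 6 HOXA genes 1 rose and 1 fell.

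Of 4 fibroblast growth factor genes tested FGF2, FGF12 and FGF13 fell and FGF5 did not pass, with FGF2 going from 137 ± 4.29 to 64.5 ± 2.74 CPM. IGF1, insulin-like growth factor 1, fell from 20.8 ± 1.26 to 2.61 ± 0.142 CPM. Of 6 bone morphogenetic growth factor genes BMP2, BMP6 and BMP8B rose and BMP3, BMP4 and BMP7 fell, with BMP2 going from 0.976 ± 0.0185 to 6.36 ± 0.3801 CPM and BMP7 at a log2 fold change of -1.35 ± 0.054. WNT ligands had 4 of 6 members higher and 1 lower, with WNT2B rising from 3.73 ± 0.262 to 12.7 ± 1.35 CPM. IGFBP2, an IGF-binding protein, fell from 59.4 ± 3.91 to 18.7 ± 1.78 CPM. Zinc finger genes of the ZNF family had 161 of 405 members lower and 59 higher. In the alternatives tried, 0 genes called there and in the main test changed direction.

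The first pattern is the shift of whole chromosome regions. GC content and gene length are argued against as its whole cause, since after their trend was removed the smallest median of the 5 broad regions was 0.339 in size. A different number of DNA copies of the 5 broad regions in the 2 cell populations is a candidate explanation: with the genes of each region divided into 3 parts by level, 15 of the 15 parts had a median with the region's sign and at least 0.2 in size. The regions had been picked from these same fold changes for a median of at least 0.2 in size. Parts of regions with medians well above that were likely to reach it, so the result does not single out DNA copies. A coordinated change of regulation is not excluded, and no DNA data were used here. In the chromosome 12 region 1 of the 3 parts, that with the highest levels, had a median of -0.026, against 0.66 and 0.41 in the others. The region's own median of 0.20 was at the cutoff and its parts held only 12 or 13 genes. A part under 0.2 was therefore likely in any case, and the check cannot decide for or against copies there. Whether inactivation of ABL1 and ABL2 led to the shifts stays open and untested.

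The second pattern is the breadth of the changes. The changes were not confined to the shifted regions, since 56.7% of the genes outside them on chromosomes 1 to 22 and X changed. This check covers position only, so it cannot tell whether the shifts led to changes elsewhere. An effect of ABL1 and ABL2 inactivation and any other difference between the cell populations stay open.

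The third pattern is the genes that differ at least 16-fold by their fitted value, 52 higher and 76 lower. Low counts in the higher group are argued against for most of them, since 69.5% had at least 100 reads there. All had been chosen past the threshold, and the counts of the lower group were not part of this check. It therefore cannot decide how far counting noise in the lower group enlarged their folds. Of these genes 10.2% lie in shifted regions. For all 128 genes, different founder cells of the populations cannot be told apart from the inactivation, because the labels do not say how many populations were made per group.

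The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes control and inactivated libraries, so the difference between the groups adds to the spread within each side. The gene counts of those splits are therefore no measure of how many calls chance would give. For the number of changed genes 1 split, the real one, gave as many (8726), and the highest of the others was 0 by edgeR, with 48 to 270 genes at an unadjusted p under 0.05. For genes changed at least 2-fold 1 split gave as many (1886), and the highest other was 0. For lists 1 split gave as many (19), and the highest other was 10. The sides of the mixed splits hold unequal numbers of inactivated libraries, so part of the group difference remains between them. Their list calls are therefore no measure of how many calls chance would give either.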
